A study of Homo sapiens with 6 samples.

How the data were processed

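RNA sequencing was done on 6 libraries of ARPE-19, an established human retinal pigment epithelium cell line. In 3 libraries the cells had been transfected with miR-204-5p, a microRNA abundant in the retinal pigment epithelium, and in 3 with the control labelled miR-NC. Per the labels' protocols, poly(A) RNA was selected, fragmented, and made into strand-marked libraries with dUTP, which were read as paired ends of 150 bases. The submitters describe the replicates as biological.

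The deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) came as 1 column per library, and 0.0001 stood in the place of 0. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2 were used on the build GRCh38, with no role or order given. The annotation release and filters are not given in the sources used here. The authors' deposited table also held a fold ratio per gene and its log2, which equalled the log2 ratio of the mean FPKM of the groups. A p-value and a q-value per gene stood beside them in the deposited table, and the tool behind them is not given in the sources used here.

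The main test had been planned on counts. The unit in hand was FPKM, so the planned replacement was used: limma 3.58.1 (R 4.3.3) with an intensity trend on log2(FPKM + 1), without covariates, for genes with an FPKM of at least 0.5 in at least 3 libraries. Values of 0.0001 were set to 0. Of 60612 genes, 13151 were tested. P-values were adjusted over genes by the Benjamini-Hochberg method, with a threshold of 0.05, and a log2 fold change of at least 1 in size marked 2-fold changes. Fold changes are miR-204-5p minus miR-NC on the log2(FPKM + 1) scale, which understates the change of low genes. Interval bounds are 95% limits from the same fit. Tests were two-sided. FPKM is a share of the library, so an RNA that takes much of 1 library lowers all its other values.

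Depth was estimated from the most frequent value of FPKM times length in single-transcript genes, taken as the step of 1 read pair. That gave the equivalent of about 19000000 to 23300000 read pairs per library. Of the values compared, up to 5.5 steps, only 36.2% to 45.0% per library lay within 1% of a multiple of 0.5 steps, so the depths are rough. At the lowest depth an FPKM of 1 in a transcript of 2 kb corresponds to 38.0 pairs, so values far below 1 rest on few reads.

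Before the data were examined, 25 gene lists, the rule for named genes and the tests were fixed. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 25 lists. Camera with an estimated correlation and fry were run beside it. The list of literature targets was written from general knowledge of miR-204. It was not chosen on these libraries. Of 865 list entries, 3 matched no symbol in the table. The rule for named genes took the 6 largest rises and falls past the threshold, up to 3 called members of each list, and the 6 largest falls past the threshold with an 8mer site, none of which existed here. It also took 11 genes named whatever they showed, and the 3 genes with the smallest adjusted p in each direction. The adjusted p-values were tied near 1, so the unadjusted p ordered the latter. Any other gene named below was chosen after its values were seen.

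Sites of miR-204-5p were searched in the longest annotated 3' UTR of each protein-coding gene, rebuilt from stop codons and exons of GENCODE release 29 (GRCh38). Of the genes tested, 10833 had such a sequence. The classes were 8mer (AAAGGGAA), 7mer-m8 (AAAGGGA), 7mer-A1 (AAGGGAA) and 6mer (AAGGGA). Genes with an 8mer or 7mer-m8 site were compared with genes without any site. The statistic was the difference of median log2 fold change, tested with 100000 permutations of the genes within deciles of UTR length. The smallest p these can give is 1e-05. Permuting genes takes them as independent, which they are not. Python 3.11.15 with numpy 2.4.6 was used.

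Simulated data held 13151 genes with independent noise, of which 100 were changed by 1 and 100 by 2 on the log2 scale. The changed genes were drawn from those with a mean log2(FPKM + 1) over 2, so recovery among lower genes was not measured. The limma test recovered 35% and 71%, with 10 false calls. With the main axis of variation between these libraries kept in the simulation, it recovered 13% and 70%, with 0 false calls. With the library axis as a covariate, the alternative added after seeing the data, it recovered 60% and 87% there and 6% and 51% with independent noise, with 3 false calls in each, and on the measured data that fit called 0 genes. Camera recovered a simulated list raised by 0.5 and called 0 other lists, with independent noise only. In the site test on 10833 genes, a planted shift of -0.10 came back as -0.10. There the residuals of a regression on UTR length, GC content and expression were shuffled over genes, so no effect of UTR length was left to correct. A shift as small as the -0.033 measured beyond UTR length was not planted. Independent noise and shuffling both remove the dependence between genes, so they do not measure false calls on these libraries.

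Alternatives were a pseudocount of 0.1, no filter, leaving out each library, the replicate number as a block, an estimated inter-gene correlation, the shortest 3' UTR of at least 50 bases, no length matching and 8mer sites alone. Added after seeing the data were median-of-ratios scaling, quantile normalization, the first residual component as a covariate, centring within length deciles, and a regression on 3' UTR length, GC content and expression.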

Results

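The series was made to look for possible targets of miR-204-5p in retinal pigment epithelium cells, and its title places the work in oxidative stress in myopia. Transcript levels in ARPE-19 cells transfected with miR-204-5p (3 libraries) were compared with those in cells given miR-NC (3 libraries). The miR-204-5p libraries held the equivalent of about 21700000, 21000000 and 19000000 read pairs for replicates 1, 2 and 3, and the miR-NC libraries about 22300000, 23300000 and 20800000.

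The groups did not separate on the leading principal component, which held 54.1% of the variance. Replicate 3 of miR-204-5p lay at -41.1 and replicate 3 of miR-NC at -32.4, while replicate 2 of each lay at 29.6 and 33.1. Replicate 1 of miR-204-5p lay at -15.3 and replicate 1 of miR-NC at 26.1, so the axis did not follow the replicate number either. Correlations of log2 values ran from 0.931 to 0.974 within groups and from 0.924 to 0.978 between them. Replicate 3 of miR-204-5p also held more RNA that carries no poly(A) tail. Genes of the ribosomal RNA precursor took 8.28% of its FPKM sum and at most 0.462% in any other library. RN7SK, a small nuclear RNA that restrains transcription elongation, stood at 361 FPKM there and between 5.24 and 14.5 FPKM elsewhere.

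**Figure D1:**
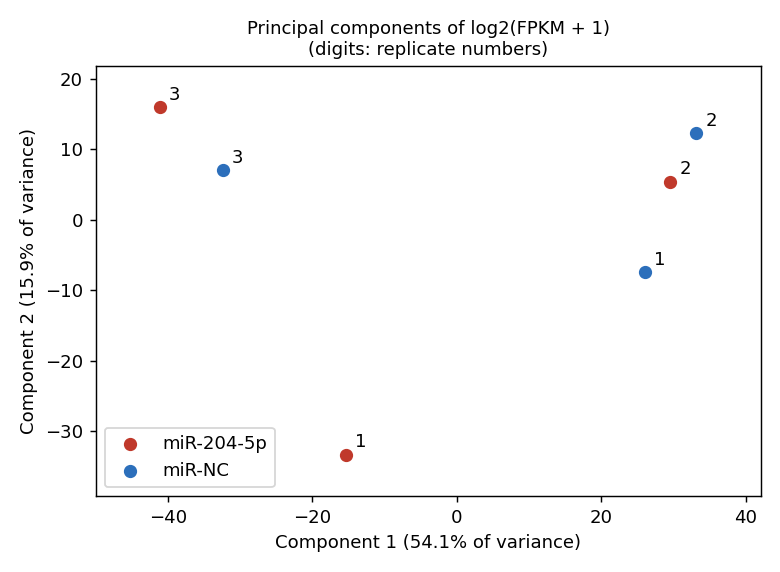
Principal components of log2(FPKM + 1) for the 6 libraries, with component 1 (54.1% of variance) on the horizontal and component 2 (15.9%) on the vertical axis, points colored by group and marked with replicate numbers. Libraries of both groups lie at both ends of component 1.

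No single gene passed the test. Of 13151 genes, 0 had an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 0 were called at 2-fold or more. An unadjusted p under 0.05 was reached by 273 genes, 152 higher and 121 lower with miR-204-5p, where 658 would be expected if p-values were uniform. The balance of directions depended on the scaling, with 134 higher and 150 lower after median-of-ratios scaling and 182 and 150 after quantile normalization. In 782 genes (5.95%) the values of one group all lay on one side of the other, which chance gives for 10% of genes. Without miR-204-5p replicate 2, 3 genes were called, and these were RPS26P19, ABLIM3 and UCN2. In each of them that library lay near the miR-NC values and apart from the other 2 of its group: it held 0.20 FPKM of RPS26P19 against 35.2 and 30.6, 16.0 FPKM of ABLIM3 against 1.48 and 1.28, and 4.20 FPKM of UCN2 against 0 and 0.

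The genes with the smallest p-values are given as values. SCARB2, a lysosomal membrane receptor, stood at 9.52 ± 2.19 FPKM (SD, n = 3) with miR-204-5p and 3.43 ± 0.63 FPKM (SD, n = 3) with miR-NC. Its log2 fold change was 1.24 with a standard error of 0.21. AP5S1, an adaptor protein subunit, stood at 3.31 ± 0.17 against 1.34 ± 0.22 FPKM (SD, n = 3 each). AP5S1 was higher although its 3' UTR holds 7mer-m8 sites of miR-204-5p. MT1M, a metallothionein that binds metal ions, stood at 5.85 ± 1.22 against 2.61 ± 0.14 FPKM (SD, n = 3 each). On the lower side, the non-coding CTBP1-DT stood at 0.22 ± 0.16 against 1.72 ± 0.32 FPKM (SD, n = 3 each). FTH1P10, a ferritin heavy chain pseudogene whose reads can be shared with its parent gene, stood at 3.90 ± 3.14 against 22.9 ± 6.45 FPKM. SNORA20, a small nucleolar RNA, stood at 0.07 ± 0.12 against 1.04 ± 0.39 FPKM, and was listed at 0 in 2 libraries. With a pseudocount of 0.1 the log2 fold changes of these low genes were larger, from -1.16 to -2.62 for CTBP1-DT and from -0.93 to -2.94 for SNORA20.

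In the authors' deposited table, 194 genes were marked as changed, 89 up and 105 down. The largest p among them was 0.0496 and the smallest absolute log2 fold change 1.01. Of the marked genes, 178 had a q of 0.05 or more in the authors' deposited table, and 16 genes had a q under 0.05. Of the marked genes in the authors' deposited table, 67 had an FPKM under 0.5 in at least 4 libraries. CTBP1-DT had a q of 0.00146 and SCARB2 a q of 0.0337 in the authors' deposited table.

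Among the genes named in advance, several with an 8mer site had lower means with miR-204-5p, and none passed the adjusted test. EZR, a linker of membrane and actin, stood at 126 ± 14.6 FPKM against 182 ± 14.7 FPKM (SD, n = 3 each), a log2 fold change of -0.52 (95% limits -0.92 to -0.13). RAB22A, a small GTPase of endosomes, stood at 2.64 ± 0.63 against 5.42 ± 1.52 FPKM. Its log2 fold change was -0.80 (95% limits -1.39 to -0.22). TXNIP, which binds and inhibits thioredoxin, stood at 0.95 ± 0.64 against 2.31 ± 0.38 FPKM, with a log2 fold change of -0.82 (95% limits -1.48 to -0.16). That was -0.52 without miR-204-5p replicate 1, which held 0.23 FPKM, and -1.47 with a pseudocount of 0.1. For EZR, RAB22A and TXNIP the 3 values with miR-204-5p all lay below the 3 with miR-NC. TGFBR2, a TGF-beta receptor, stood at 6.93 ± 3.29 against 13.8 ± 5.52 FPKM with overlapping values, and its limits of -1.85 to 0.06 included 0. AP1S1 and AP1S2, subunits of a clathrin adaptor, had log2 fold changes of -0.30 (limits -0.70 to 0.09) and -0.56 (limits -1.06 to -0.07). AP1S1 holds an 8mer, but AP1S2 only a 6mer. For both, all miR-204-5p values also lay below all miR-NC values, for AP1S1 narrowly. MEIS2, a homeobox factor with 7mer-A1 sites and no 8mer, had -0.53 (limits -1.25 to 0.18). That was -0.84 without miR-204-5p replicate 2, -0.28 without replicate 3 and -1.35 with a pseudocount of 0.1. SIRT1, a deacetylase, had -0.07 (limits -0.51 to 0.37), and ran from -0.24 without miR-NC replicate 3 to 0.059 without miR-NC replicate 1. SNAI2, BCL2 and TRPM3, the host gene of the microRNA, were below the filter. Mean FPKM with miR-204-5p and miR-NC was 0.011 and 0.0046 for SNAI2, 0.12 and 0.099 for BCL2, and 0.035 and 0.038 for TRPM3. Of these, BCL2 holds an 8mer, and its mean was not lower with miR-204-5p.

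**Figure D2:**
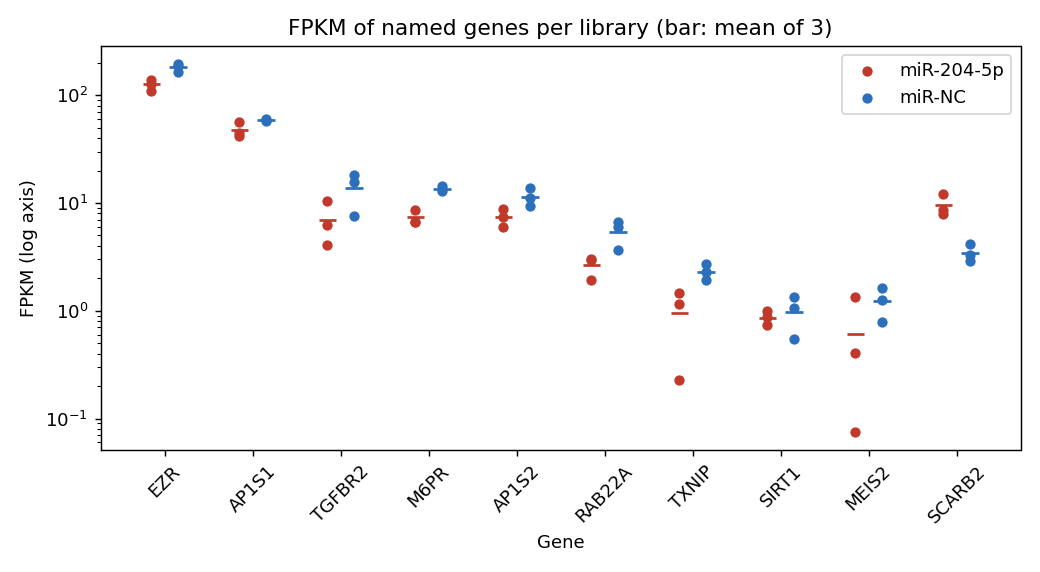
FPKM on a log axis of 10 genes in the 3 miR-204-5p and 3 miR-NC libraries, each point a library and each bar a mean. EZR, AP1S1, M6PR, AP1S2, RAB22A and TXNIP lie lower in each miR-204-5p library, TGFBR2, SIRT1 and MEIS2 overlap, and SCARB2 lies higher. Of the 10, 0 passed the adjusted test.

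These sites lie in 3' UTRs on GRCh38. The 8mer of TXNIP is at chromosome 1, 145993398 to 145993405, and that of EZR at chromosome 6, 158766188 to 158766195. TGFBR2 has its 8mer at chromosome 3, 30693923 to 30693930, and SIRT1 at chromosome 10, 67916977 to 67916984. RAB22A has 8mers at chromosome 20, 58360031 to 58360038 and 58362944 to 58362951.

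As a group, the literature targets of miR-204 were lower. Of 27 tested members 26 had negative fold changes, the median was -0.30, and the list passed camera (limma, adjusted p = 1.06e-09). With an estimated correlation the adjusted p = 0.937. No member fell when adjusted over all genes, and 1 did when adjusted over the list alone, M6PR, a sorting receptor for lysosomal enzymes (adjusted p = 0.0485, limma). M6PR, named after its values were seen, stood at 7.35 ± 1.15 against 13.6 ± 0.79 FPKM (SD, n = 3 each). In 9 members all miR-204-5p values lay below all miR-NC values.

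Genes of hypoxia and angiogenesis were lower as a list (28 of 33 negative, median -0.23, camera adjusted p = 1.58e-04), and the adjusted p = 0.937 with an estimated correlation. The call ended without miR-204-5p replicate 1 (adjusted p = 0.0824, limma). Among its members, chosen after their values were seen, the glycolytic enzymes PGK1 and HK2 had log2 fold changes of -0.46 and -0.42, the latter -0.25 without miR-204-5p replicate 1 and -0.63 without replicate 2. Collagens and basement membrane genes were lower (29 of 37 negative, median -0.16, camera adjusted p = 0.0024, and adjusted p = 0.937 with an estimated correlation). The call ended without miR-204-5p replicate 1 (adjusted p = 0.430, limma) and without miR-NC replicate 2 (adjusted p = 0.133, limma), and without a filter (0.210). SPARC, a matrix glycoprotein chosen after its values were seen, had a log2 fold change of -0.45. Nuclear oxidative phosphorylation genes were higher (34 of 44 positive, median 0.13, camera adjusted p = 0.042, and adjusted p = 0.937 with an estimated correlation). That call ended without miR-204-5p replicate 1 (adjusted p = 0.430, limma) or replicate 3 (0.527), and without miR-NC replicate 1 (0.465) or replicate 2 (0.875). It also ended without a filter (0.0509), with median-of-ratios scaling (0.124) and with quantile normalization (0.490). In these lists 0 members rose or fell over all genes or adjusted over the list alone.

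**Figure D3:**
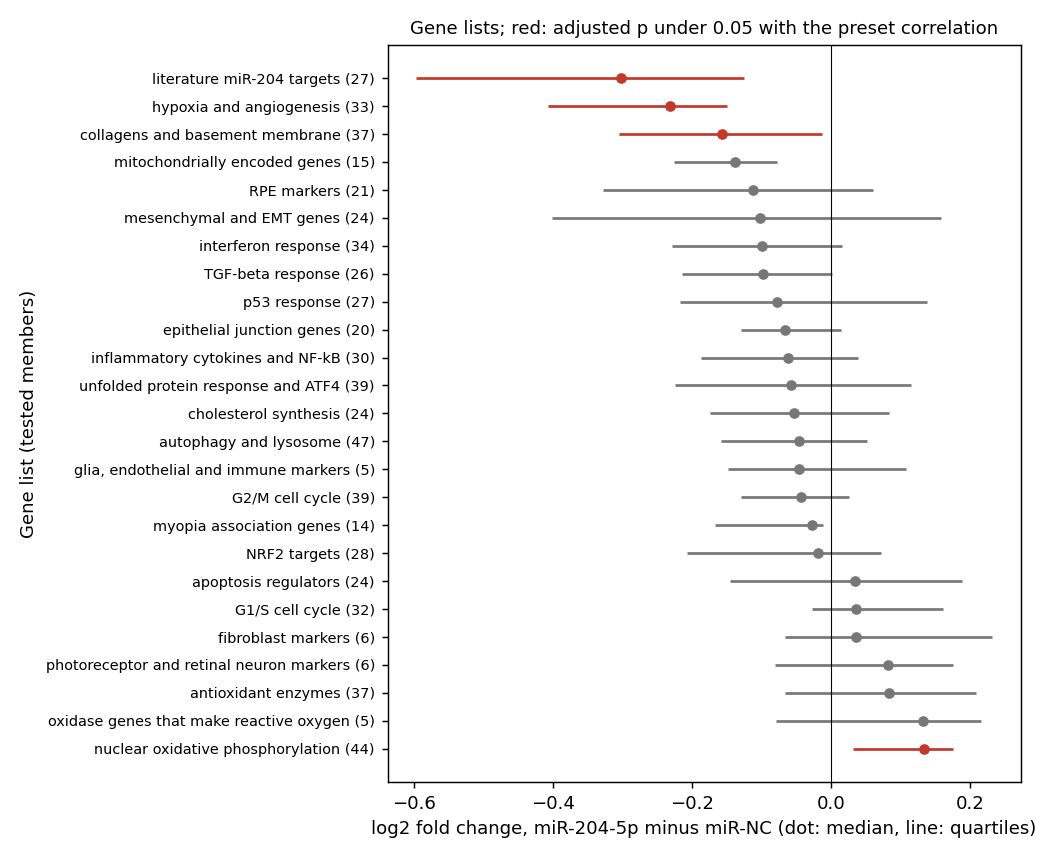
Median (dot) and quartiles (line) of log2 fold change for 25 gene lists, with tested members in brackets and red for lists with adjusted p under 0.05 at the preset correlation. Literature targets lie lowest at -0.30 and nuclear oxidative phosphorylation highest at 0.13, and 0 lists passed with an estimated correlation.

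Oxidative stress genes did not pass as lists. Among antioxidant enzymes 25 of 37 were positive with a median of 0.08 (camera adjusted p = 0.483). The 37 include TXNIP, the inhibitor of thioredoxin named above, which had a log2 fold change of -0.82. The antioxidant list was called higher without miR-204-5p replicate 2 (adjusted p = 0.0183, limma) and without miR-NC replicate 3 (adjusted p = 0.00439, limma). PRDX6, a peroxiredoxin, and TXN2, mitochondrial thioredoxin, had log2 fold changes of 0.32 and 0.34, while GSR, glutathione reductase, had -0.53. These were chosen after their values were seen. NRF2 targets were 15 negative and 13 positive with a median of -0.02 (camera adjusted p = 0.469). NQO1, a quinone reductase chosen after its values were seen, had -0.41. The 5 tested oxidase genes had a median of 0.13 (camera adjusted p = 0.791).

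The remaining lists were not called. Medians and camera adjusted p-values were -0.10 and 0.177 for the TGF-beta response, -0.14 and 0.381 for mitochondrially encoded genes, and -0.11 and 0.381 for RPE markers. They were -0.05 and 0.469 for autophagy and lysosome, -0.10 and 0.483 for the interferon response, and -0.10 and 0.483 for mesenchymal and EMT genes. They were 0.04 and 0.483 for G1/S, -0.04 and 0.672 for G2/M, -0.06 and 0.531 for inflammatory cytokines, and -0.03 and 0.531 for myopia association genes. They were -0.06 and 0.574 for the unfolded protein response, -0.07 and 0.584 for epithelial junctions, 0.03 and 0.791 for apoptosis regulators, and -0.08 and 0.791 for the p53 response. Photoreceptor and neuron markers had 0.08 and 0.791, fibroblast markers 0.04 and 0.791, cholesterol synthesis -0.05 and 0.912, and glia, endothelial and immune markers -0.05 and 0.961. For the last pair of lists the sign of the median differed from the direction of the test. Some were called under alternatives. The TGF-beta response was called lower without miR-204-5p replicate 2 (adjusted p = 0.00855, limma) and without miR-NC replicate 3 (0.0333), and with the library axis as a covariate (0.0475), as were mitochondrially encoded genes with that covariate (6.13e-04). G1/S genes were called higher without miR-204-5p replicate 3 (adjusted p = 0.00168, limma), and inflammatory cytokines lower without miR-NC replicate 1 (0.0163). The interferon response was called lower without miR-204-5p replicate 3 (adjusted p = 4.94e-09, limma), miR-NC replicate 1 (1.26e-06) or miR-NC replicate 2 (0.0491), and higher without miR-204-5p replicate 1 (0.0337) or miR-NC replicate 3 (0.00296).

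Transcripts with a seed site were lower than those without. The median log2 fold change was -0.09 for 2023 genes with an 8mer or 7mer-m8 site and 0.01 for 6522 genes without a site. That is a difference of -0.10, where -0.064 was the mean over permutations within length classes and -0.033 lay beyond it (permutation of genes, p = 1e-05, the smallest possible). The same p was under 0.05 in 7 of the 9 other splits of the libraries and 1e-05 in 2 of these, and each such split kept part of any difference between the groups. The difference was -0.17 without miR-204-5p replicate 2 and -0.16 without miR-NC replicate 3, and -0.061 without miR-204-5p replicate 3 and -0.064 without miR-NC replicate 2. By class, the median was -0.11 for 937 genes with an 8mer, -0.08 for 7mer-m8, -0.06 for 7mer-A1 and -0.02 for 6mer. Beyond what UTR length gave, the differences from genes without a site were -0.052 for 8mer, -0.027 for 7mer-m8, -0.012 for 7mer-A1 (permutation of genes, p = 0.103) and 0.0079 for 6mer (permutation of genes, p = 0.257). Without matching for UTR length, 72.3% of the 8mer genes were negative, 55.7% of the 6mer genes and 48.3% of the genes without a site. An unadjusted p under 0.05 (limma) was reached by 31 lower and 3 higher 8mer genes, 8 lower and 14 higher 6mer genes, and 34 lower and 76 higher genes without a site. Camera on the 8mer and 7mer-m8 set gave p = 1.15e-05, and p = 0.414 with an estimated correlation. By the difference of medians the 7mer AAAGGGA ranked 66 and AAGGGAA 231 of 15718 7mers. None of the genes was called adjusted over the set alone.

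The gene permutation does not measure the spread between libraries. A site score per library, centred for UTR length, averaged -0.021 ± 0.0098 (SD, n = 3) with miR-204-5p and 0.025 ± 0.0040 (SD, n = 3) with miR-NC. The groups did not overlap, and the exact permutation p = 0.1 was the smallest that 3 against 3 allows.

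**Figure D4:**
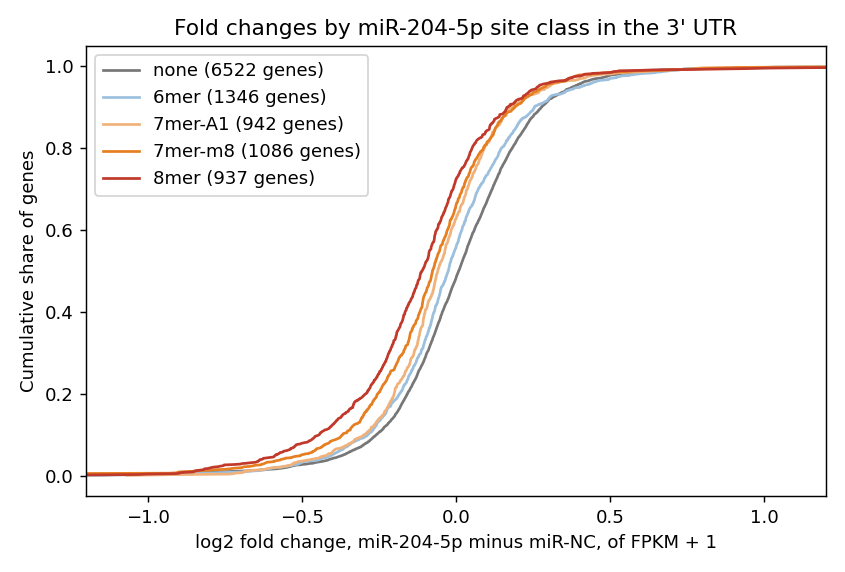
Cumulative share of genes against log2 fold change (miR-204-5p minus miR-NC, of FPKM + 1) for genes with an 8mer, 7mer-m8, 7mer-A1, 6mer or no site in the 3' UTR. The 8mer curve lies farthest left, with a median of -0.11 against 0.01 for genes without a site, before any matching for UTR length.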

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

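The count-based alternatives (other count scalings, other count tests and count filters, and FPKM beside counts) were not run, because the values used here were FPKM. Calls of single genes stayed at 0 under all alternatives run except without miR-204-5p replicate 2, so leaving out single libraries gave 0 to 3 genes, and 0 to 3 at 2-fold or more; the cause was not tested. Genes at an unadjusted p under 0.05 (limma) numbered 273, and 725 of 29806 without a filter. They numbered 284 and 332 with the added scalings, and 156 (without miR-204-5p replicate 1) to 740 (without miR-204-5p replicate 2) when leaving out single libraries. With the library axis as a covariate they numbered 1598. That covariate is taken from the residuals of each fit. With it the other splits of the libraries gave 645 to 6297 such genes, so 1598 does not set the real split apart. Of 322 list values under alternatives, 293 stayed on the same side of the threshold, 29 of them with the direction of an uncalled list turned, 15 lost the call, 12 gained it in the same direction and 2 gained it in the other. Lists called numbered 4, then 2 without a filter, 0 with an estimated correlation, and 2 to 7 when leaving out single libraries (2 without miR-204-5p replicate 1, 7 without miR-NC replicate 3). The interferon response changed direction and was called without miR-204-5p replicate 1 (adjusted p = 0.0337, limma) and without miR-NC replicate 3 (0.00296), with a range of 4.94e-09 to 0.629 over left-out libraries. SIRT1 was 0.059 without miR-NC replicate 1 and ran from -0.24 to 0.059. The other 433 of 434 values of named genes kept their direction. The difference for seed sites stayed negative with a gene permutation p = 1e-05 in each alternative, from -0.17 to -0.032. It was -0.032 after centring and -0.038 after the regression, both added after seeing the data.

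With the replicate number as a block, 0 genes and 5 lists were called, the fifth being the TGF-beta response (adjusted p = 0.0460, limma), and 941 genes had an unadjusted p under 0.05. Deviations of same-numbered libraries correlated at 0.04, 0.55 and 0.52 for replicates 1, 2 and 3. Unlike-numbered libraries ran from -0.61 to 0.32, so replicates 2 and 3 correlated best with their own number. In contrast, miR-204-5p replicate 1 correlated best with miR-NC replicate 3 (0.16). The block was left out of the main fit in advance, because the titles do not say that a number marks a shared day. Whether the numbers mark pairs stays open.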

Other observations

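Tests on the library axis, the splits of the samples and the site shift were chosen or completed after related results had been seen, while the comparisons of lists with random lists and of the passenger strand were set before theirs. The regression on UTR length, GC content and expression was also added after seeing the data.

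Other genes with an 8mer site and small p-values, chosen after their values were seen, were SERINC3, MANEAL, BIRC2 and FZD4. SERINC3, a membrane protein, stood at 12.2 ± 3.52 against 25.3 ± 5.53 FPKM (SD, n = 3 each). BIRC2, an inhibitor of apoptosis, stood at 6.01 ± 0.94 against 9.75 ± 1.45 FPKM, and FZD4, a Wnt receptor, at 2.08 ± 0.34 against 3.40 ± 0.29 FPKM. None passed the adjusted test.

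The main axis of variation did not separate the groups, but it was not balanced between them. Component 1 was -15.3, 29.6 and -41.1 with miR-204-5p and 26.1, 33.1 and -32.4 with miR-NC, so the axis can enter the fold changes. The lowest miR-NC site score lay 0.0367 above the highest miR-204-5p score, so no library had a score on the other group's side. Whether labels were swapped between the groups cannot be decided from it. The site scores reached only an exact permutation p = 0.1, and the criterion takes the site shift as an effect of miR-204-5p. Gene loadings correlated across genes (Spearman) with UTR GC content at -0.44, with UTR length at 0.39 and with mean expression at -0.23. A bias by transcript composition may therefore contribute, and genes are not independent. Carry-over of RNA without a poly(A) tail stays open. For 2 of 5 measures (RN7SK and RN7SL1) each library on the negative side of the axis lay above each on the positive side.

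For transcripts with a site, the 10 splits are too few for a share under 0.05; 3 of them, the real one included, had a difference as large in size, with 0.10 for the real split and 0.21 for the highest other, while beyond UTR length the real split was the largest of the 10 (0.033 in size against 0.024 for the highest other). Ranks of AAAGGGA depended on the ranking: of 5 tried it was 66, 69, 44 and 3, and 1 only after the regression, the last one chosen. As that ranking was chosen after the others were seen, it cannot decide whether UTR length, GC content and expression are the whole cause. The regression on these left a difference of -0.038 between genes with and without a site. After the regression the 8mer shift was -0.045, followed by -0.029 for 7mer-m8, -0.0087 for 7mer-A1 and -0.0030 for 6mer, which is consistent with pairing to the seed as a hypothesis. The 7mer of the passenger strand miR-204-3p ranked 10125 after the regression and from 7995 to 14113 in the other rankings. Transcripts with it were thus not among those that fell most, and a small effect of that strand was not tested.

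The same 10 splits are too few for the counts of calls. The real split gave 0 genes (10 of 10 splits gave as many, highest other 4036), 0 genes at 2-fold (10 of 10, highest other 475) and 4 lists (7 of 10, highest other 11). The split with 4036 genes, miR-204-5p replicates 1 and 3 with miR-NC replicate 3 against the rest, divided the libraries by the sign of the main axis, so its calls restated that axis. Each other split set 2 libraries of one group with 1 of the other and so kept part of any difference between the groups.

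After the regression, median residuals were -0.30 for literature targets, -0.25 for hypoxia and angiogenesis and -0.17 for collagens. All lay below the central 95% of 10000 matched random lists. Random lists were drawn gene by gene, so their range is too narrow where members vary together. Estimated inter-gene correlations were 0.41, 0.13 and 0.45 for these lists, so the range cannot decide whether composition was the whole cause. Members without any site had -0.29 in the hypoxia list and -0.15 in the collagen list, also below that range. The lower values were therefore not confined to members with a site. Nuclear oxidative phosphorylation, at 0.080, lay inside the range, so composition may account for it. Of 24 lists 7 lay outside, where 1.2 would by chance if genes were independent, and the cause of the excess was not tested; the other 4, all below, were mesenchymal and EMT genes (-0.12), NRF2 targets (-0.095, where the median before the regression was -0.02), the interferon response (-0.088) and the TGF-beta response (-0.078), and their members without any site had 0.13, -0.11, -0.071 and -0.11, the first inside the range and of the opposite sign. A difference between cultures, which the design does not separate from the transfection, stays open.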
